A study of Sinohyriopsis cumingii with 2 samples.

How the data were processed

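Small RNA libraries of mantle exosomes from 1 white and 1 purple group of mussels were compared. Per the labels, adaptors were ligated to exosomal RNA, which was then reverse transcribed, amplified and size selected, and read on a HiSeq instrument over 50 cycles. How many animals went into each library is not given in the sources used here. The submitters' processing notes name cutadapt 1.9.2 and Novoalign 3.02.12 without their settings. The reference catalogue and genome build are not given in the sources used here. Entry names carry 72 species prefixes of the kind used in public miRNA catalogues, 42 of vertebrates and 24 of protostomes.

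A pair of sheets with the same 1404 entries were deposited. Per the file headers, the first holds raw tag counts. These are estimated counts that the authors rounded to whole numbers: dividing the normalized values by the multiplier given below puts white entries listed at 2 between 1.56 and 2.56 tags, and purple ones between 1.45 and 2.54. Cells below 2 tags are empty, so an empty cell was read as under 2 tags and not as 0, except in sums of tags. The second deposited sheet holds normalized tag counts, recorded here as a score because its unit is not stated. Within rounding, they equal the unrounded tags times 1 multiplier per library, 7.04 in white and 5.50 in purple. Ratios under the deposited scaling apply these multipliers to the listed raw tags. If the normalized values are CPM, the totals behind them would be about 142094 and 181690 tags. The listed sequences, each counted once, would be 1.28% and 1.73% of these. The part would be larger if tags were divided among entries, which sum to 21059 in white and 32530 in purple. The listed total may thus not be the depth of either library. The columns are headed only with a number, and each was matched to the library whose title ends in that number. No column of per-sample values was left unmatched.

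The 1404 entries hold 170 distinct sequences, and all entries of a sequence carried the same counts, for up to 89 entries. Before the data were examined, the plan had been to treat 1 entry as 1 miRNA. If every entry carried the full count of its sequence, that would count the same tags many times. Each distinct sequence was therefore taken as 1 miRNA, and the values over all entries are an alternative. The sources used here do not say whether tags were instead divided evenly among the entries of a sequence. The fractional counts leave such a division possible. A sequence counted once would then be understated by its number of entries. The sum over entries was 21059 tags in white and 32530 in purple, a ratio of 1.54. A sequence is called by its human entry name where it has one, and otherwise by the first of its names. A family joins all sequences that share a number, such as miR-451. Tags of length variants were summed within a family only. How the authors shared reads between overlapping entries is not stated, so the split between length variants and between near-identical let-7 members is uncertain.

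Counts were scaled to the total of the listed distinct sequences. The log2 ratio of purple to white was taken after adding 0.5 to each count, with a 95% exact conditional binomial (Clopper-Pearson) interval. For single sequences an empty cell entered at 2 tags. In family sums it added no tags, unless the whole family was empty in a library, which then entered at 2 tags per sequence. A sequence was called when it had at least 10 CPM in a library, a ratio of at least 2-fold and an interval excluding 0. Since 1 tag is worth more than 10 CPM, that filter removed no sequence. With 1 library per group, no test of the difference between mussel types was possible. List medians used families with at least 10 tags and were placed among 10000 random lists, each member drawn from the 10 families nearest in abundance. Percentages carry exact binomial intervals. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. The rule and its intervals were tested on data simulated with counting error only, known totals and listed counts treated as whole reads. There 97.8% of the intervals of sequences listed in both libraries held the true ratio.

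Named in the text, by a rule fixed in advance, are the 10 most abundant sequences, up to 10 called sequences per direction, and up to 4 families with the most tags from each of 12 lists. The lists cover let-7, muscle, neural, epithelial, sensory, pigment cell, shell, protostome, miR-1984 to miR-1996, other bilaterian, vertebrate and plant families. Other families are named as those whose interval excluded 0 here or under another scaling, and were chosen after their values were seen. Alternatives were the scalings of edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (size factors), the deposited scale, totals without a leading sequence, other filters, folds and added counts, and sums per family. The 4 further lists used in the closing observations (red cell, white cell, other vertebrate tissues, and fragments of other non-coding RNA) were chosen after the family values had been seen. Analyses used Python 3.11.15, scipy 1.17.1 and R 4.3.3.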

Results

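Small RNAs were sequenced from exosomes, the small vesicles that cells release, isolated from the mantle of the freshwater pearl mussel Hyriopsis cumingii. The mantle is the tissue that lays down the shell and its nacre. The mussels were about 2 years old with a mean shell length of 9 cm, and they belonged to a white and a purple type. Each type was represented by 1 library, so no difference between them has a replicate check and no p-value is given. The deposited table held 1404 catalogue entries, but these named only 170 distinct mature sequences of 17 to 26 nt, because the same sequence recurred under the names of many species. Each distinct sequence was therefore counted once. Whether the tags of a sequence were repeated or divided among its entries is not known. If they were divided, the shares, CPM values and intervals below would change. The white library held 1820 tags on these sequences and the purple library 3141 tags, so that 1 tag was worth 549 CPM of the listed tags in white and 318 CPM in purple. Of the 170 sequences, 123 had fewer than 10 tags in both libraries. All intervals below are 95% exact intervals that cover counting error only, not the variation between animals or between exosome preparations. No genome coordinates are given, since no mussel genome was used here.

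The first question was which miRNAs the mantle exosomes carried. With each sequence counted once, the miR-451 family, a vertebrate miRNA abundant in red blood cells, was the largest in both libraries. It held 21.6% of the listed tags in white (interval 19.7 to 23.6) and 15.3% in purple (14.1 to 16.7). The rankings here could change if tags were divided among entries. The sequence hsa-miR-451a had 11 entries, against 19 for hsa-let-7i-5p and 34 for hsa-let-7f-5p. The let-7 family, a regulator of developmental timing across animals, came next in white with 16.2% and held 12.9% in purple. The miR-151 family held 10.8% in white and 13.2% in purple, the miR-148 family 7.25% and 8.91%, and the miR-21 family 5.27% and 6.21%. The single most abundant sequence, hsa-miR-451a, took 18.6% of the white tags (16.8 to 20.4) and 13.4% of the purple tags (12.2 to 14.6). The 10 leading sequences together took 59.1% of the white tags and 62.7% of the purple tags. At the listing minimum of 2 tags, 125 sequences were present in both libraries, 11 in white alone and 34 in purple alone. When the purple library was thinned to the white total, a median of 121 sequences remained in purple over 100 draws, against 136 in white. The thinning took the listed totals as the depths, a purple to white ratio of 1.73, whereas the deposited multipliers put that ratio at 1.28. Across the 125 shared sequences the tag counts had a Spearman correlation of 0.87 and a Pearson correlation of 0.91 on the log2 scale. These correlations are across sequences, which are not independent replicates.

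**Figure D1:**
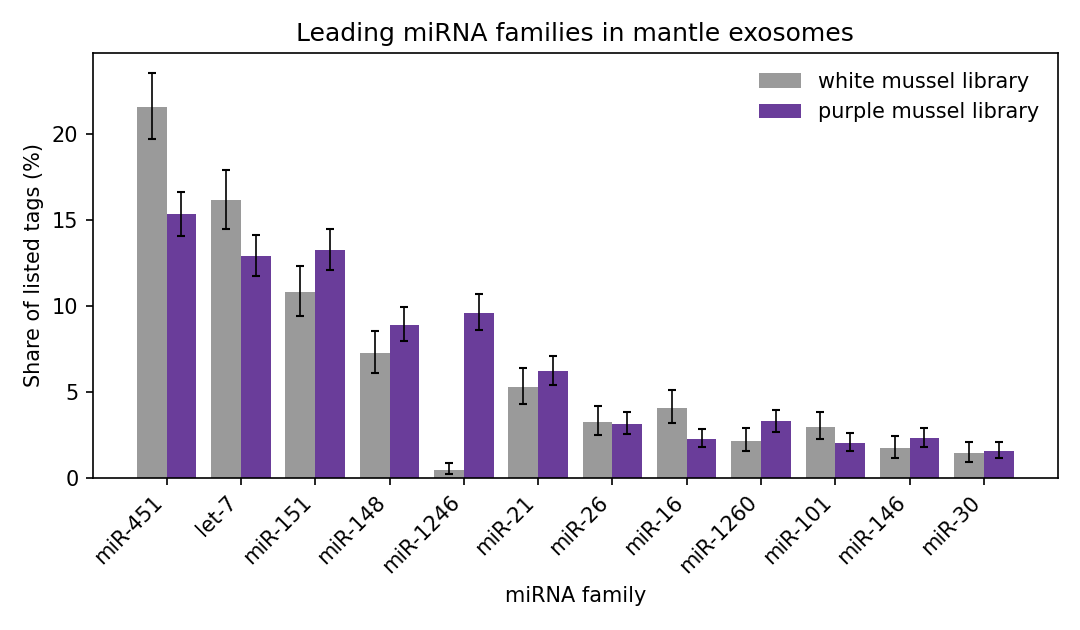
Bars give the share of listed tags (%, y axis) held by each of the 12 leading miRNA families (x axis) in the white (grey) and purple mussel library (purple), and error bars are 95% exact binomial intervals covering counting error only. With each sequence counted once, the miR-451 family led both libraries, and the miR-1246 family held 0.440% of the white tags against 9.61% of the purple tags. These shares would change if tags were divided among entries, of which hsa-miR-1246 had 3 and hsa-miR-451a 11.

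Nearly all tags lay on sequences whose deposited entries carry vertebrate prefixes alone. Entries were joined by exact sequence, so length variants and close members of families found across animals, such as let-7, count as vertebrate where no other prefix is attached. These 165 sequences held 1807 of the 1820 white tags, or 99.3% (98.8 to 99.6), and 3123 of the 3141 purple tags, or 99.4% (99.1 to 99.7). A further 2 sequences, listed also for an invertebrate outside the protostomes, held 9 white and 8 purple tags. The 3 sequences that were also listed for a protostome, the animal branch that includes molluscs, held 4 white tags and 10 purple tags. They were the 22-nt hsa-let-7a-5p with 2 and 4 tags, its 21-nt form bmo-let-7-5p with 2 and 3 tags, and hsa-miR-1-3p, which was empty in white and had 3 tags in purple. Their entries numbered 89, 21 and 42. If tags were divided among entries, these low counts would understate the sequences strongly. Entries of the owl limpet, a mollusc, were among the names of hsa-let-7a-5p and hsa-miR-1-3p. None of the 16 families in the protostome list, among them bantam, miR-2, miR-71, miR-279 and miR-317, had a listed entry. None of the 14 families in the miR-1984 to miR-1996 series with miR-2001 and miR-2722 had one, nor did the 23 plant families, the 7 neural families or the 4 epithelial families, miR-8, miR-141, miR-200 and miR-429. Of 39 families annotated mainly in vertebrates, 26 were listed, and they held 55.6% of the white tags (53.3 to 57.9) and 48.6% of the purple tags (46.8 to 50.3).

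The comparison of purple with white mussels addressed which exosomal miRNAs differ between the types, in a study of how nacre colour forms. On the share of listed tags, hsa-miR-1246 was higher in the purple library, with 302 tags against 8 in white, a log2 ratio of 4.37 (interval 3.45 to 5.68) or 20.6-fold. It was the only one of the 170 sequences that was at least 2-fold higher in purple with an interval excluding 0. This sequence matches part of the U2 small nuclear RNA of the spliceosome in vertebrates. At least 2-fold higher in white were hsa-miR-486-5p, hsa-miR-629-5p and hsa-miR-4516. The red-cell miRNA hsa-miR-486-5p had 23 white and 19 purple tags (log2 ratio -1.06, interval -2.02 to -0.12), and hsa-miR-629-5p had 15 and 11 (-1.22, interval -2.50 to -0.01). The sequence hsa-miR-4516 had 7 tags in white and was empty in purple. With the empty cell taken at the listing minimum of 2 tags, its log2 ratio was -2.37 (interval -5.90 to -0.20), and -1.94 with an interval including 0 under the scaling of the deposited normalized values. With the deposited scaling, hsa-miR-1246 had a log2 ratio of 4.80, and cgr-miR-1260, hsa-miR-4532 and oha-miR-1a-3p were also called higher in purple. With that scaling, and with 2 further scalings (TMM and DESeq2 size factors), none of the 170 sequences was called higher in white. Of the other abundant sequences, hsa-miR-151a-3p had 182 white and 378 purple tags (0.27, interval 0.01 to 0.53), hsa-miR-148a-3p 124 and 271 (0.34, interval 0.03 to 0.66) and cgr-miR-1260 39 and 103 (0.60, interval 0.07 to 1.18). Lower shares in purple were found for hsa-miR-451a with 338 and 420 tags (-0.47, interval -0.68 to -0.26), hsa-let-7i-5p with 149 and 185 (-0.48, interval -0.79 to -0.15), hsa-miR-16-5p with 64 and 59 (-0.90, interval -1.44 to -0.37) and bta-miR-451 with 45 and 47 (-0.73, interval -1.35 to -0.10). The intervals of chi-miR-21-5p, with 66 and 137 tags, and hsa-let-7g-5p, with 35 and 65, included 0. In all, 4 sequence intervals lay above 0 and 7 below on the share of listed tags, against 8 above and 0 below under the deposited scaling. There hsa-miR-451a and hsa-let-7i-5p stood at -0.04, hsa-miR-16-5p at -0.47 and bta-miR-451 at -0.29, and the interval of chi-miR-21-5p, at 0.69, lay above 0. Libraries of this depth were simulated with counting error only and known totals, so the rates leave out scaling error and noise between libraries. They also treat each listed count as whole reads, which would not hold if tags were divided among entries. There the rule called 1.06% of unchanged sequences, or 1.81 of 170. Over all 170 sequences it found 12.1% of 2-fold changes and 36.5% of 4-fold changes. Among sequences expected to hold at least 30 tags over both libraries it found 47.0% and 96.2%.

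**Figure D2:**
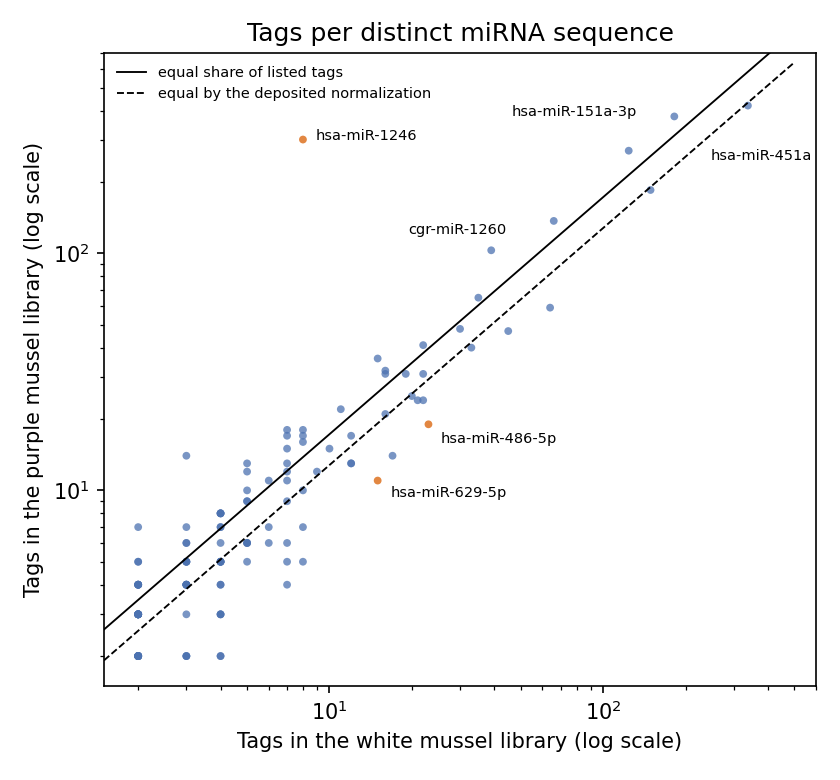
Each point is 1 of the 125 sequences listed in both libraries, with its tags in the white library (x axis, log scale) and in the purple library (y axis, log scale), and orange points differed at least 2-fold in share of listed tags with a counting interval excluding 0. The solid line marks an equal share of listed tags and the dashed line equality under the deposited normalization, and hsa-miR-1246 lies far above both with 8 white and 302 purple tags.

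The direction of many of the smaller differences depended on how the libraries were scaled. The purple library held 1.73 times the listed tags of the white library, but the multipliers behind the deposited normalized values set its depth at only 1.28 times, a shift of 0.43 on the log2 scale for every sequence. Summed over all entries, the ratio of tags was 1.54, between these values. With the listed total as the scale, 41 of the 125 shared sequences had a log2 ratio above 0 and 84 below. With the deposited scale, 74 were above and 51 below.

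The counts were then summed into 83 families, of which 46 had at least 10 tags over both libraries. On the share of listed tags, the intervals of 3 of these 46 families lay above 0 and those of 5 lay below. Above 0 were miR-1246, the miR-1260 family with 39 white and 103 purple tags (log2 ratio 0.60, interval 0.07 to 1.18), and the miR-151 family with 197 and 416 tags (0.29, interval 0.04 to 0.54). Below 0 were miR-451 with 393 and 482 tags (-0.49, interval -0.69 to -0.30), let-7 with 294 and 406 (-0.32, interval -0.54 to -0.10), miR-16 with 74 and 71 (-0.85, interval -1.34 to -0.36), miR-486 with 40 and 33 (-1.06, interval -1.78 to -0.36) and miR-629. Under the deposited scale 7 of the 46 intervals lay above 0 and none below. The added families were miR-21 at 0.66, miR-148 at 0.73, miR-146 at 0.85 and miR-4532 at 1.70, while let-7 changed sign to 0.11 and miR-451 stood at -0.06. With TMM the let-7 family stood at -0.05 and miR-451 at -0.22 (interval -0.42 to -0.03).

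**Figure D3:**
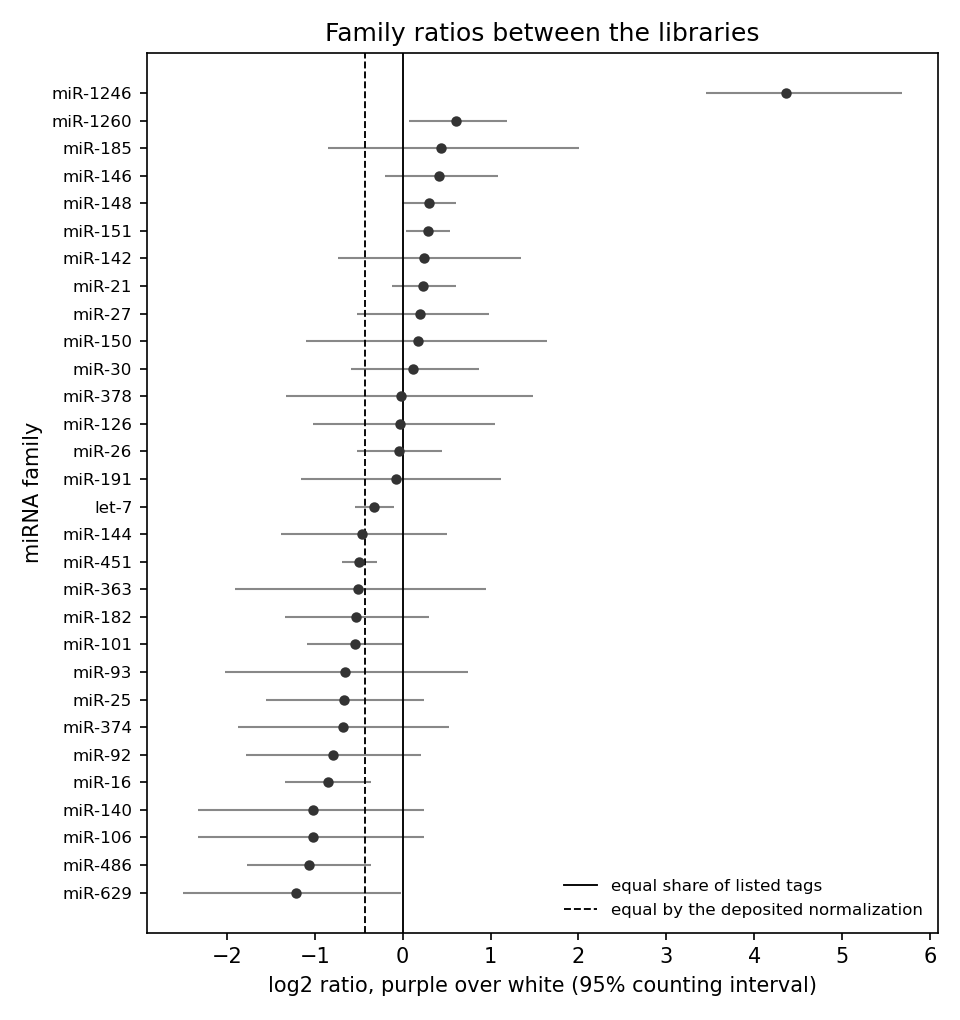
Points give the log2 ratio of purple to white tags (x axis) for the 30 families with at least 20 tags over both libraries (y axis), scaled to the listed total, and bars are 95% exact counting intervals. The solid line marks an equal share of listed tags and the dashed line equality under the deposited normalization, and miR-1246 at 4.37 is the only family whose interval lies above 3.

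The lists fixed for pigment cells, shell formation and other tissues showed few differences at this depth. The list drawn from vertebrate pigment-cell work had 7 of its 14 families measured, with a median log2 ratio of 0.04 at the 51.0 percentile of 10000 random lists of matched abundance. Among its members, miR-148 was at 0.29 (interval -0.01 to 0.61), miR-21 at 0.23 (-0.12 to 0.60), miR-182 at -0.53 (-1.34 to 0.30) and miR-101 at -0.54 (-1.09 to 0.01). None of the 7 intervals excluded 0, whereas with the deposited scale 2 lay above 0 and the median was 0.47. Of the 8 families in the shell and mineralisation list, 4 were listed, with 9 white and 6 purple tags in all. The miR-15 family had 5 white and 2 purple tags, miR-183 had 2 and 2, miR-4504 had 2 in white and was empty in purple, and miR-29 was empty in white with 2 in purple. The summed tags of this list had a log2 ratio of -1.37 with an interval that included 0 (-3.14 to 0.28). With so few tags, a small difference in these families could not be seen. The let-7 cluster list, with let-7 and miR-99 measured and miR-98 seen at 2 purple tags only, had a median of 0.17 at the 52.4 percentile, although its summed tags had a log2 ratio of -0.30, with let-7 holding 294 of 297 white and 406 of 417 purple tags. Under the deposited scaling the median was 0.60. In the muscle list, the miR-1 family was empty in white and had 15 purple tags over 2 sequences, which with the listing minimum of 2 tags for each empty sequence gave an interval of the log2 ratio that included 0 (-0.53 to 3.17). Its sequence oha-miR-1a-3p, with 12 of these tags, was called higher in purple under the deposited scaling and with empty cells taken as 0, but not on the share of listed tags at the listing minimum. In the sensory and ciliated cell list, with 27 white and 32 purple tags, miR-182 was the measured member, and of the remaining bilaterian families miR-92 had 19 tags in each library (-0.79, interval -1.78 to 0.21) and miR-22 had 3 and 4. The 22 measured families annotated mainly in vertebrates had a median of -0.06 at the 34.6 percentile, with no interval above 0 and 3 below. Under the deposited scaling the median was 0.37, with 3 intervals above 0 and none below. The miR-26 family was at -0.05 (-0.52 to 0.45), and at 0.39 under that scaling. These lists shared members, such as miR-148, miR-21, miR-182 and miR-183.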

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

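The alternatives with every entry as its own item, empty cells as 0, unrounded tags and the total without miR-1246 were chosen after seeing the data. The sequence hsa-miR-1246 was called higher in purple under each of the 6 scalings. The count higher in purple, 1 as reported, was 4 with the authors' normalized values, which added cgr-miR-1260, hsa-miR-4532 and oha-miR-1a-3p, 2 at 1.5-fold, 2 with empty cells as 0, which added oha-miR-1a-3p, and 3 with every entry as its own item, all 3 of them entries of miR-1246. The 3 sequences higher in white came to 0 with TMM, 0 with DESeq2 size factors and 0 with the authors' normalized values. They came to 5 at 1.5-fold, 1 at 4-fold, 1 without miR-1246 in the total, and 1 with every entry as its own item. The scalings that gave none in white shift every log2 ratio upward by 0.20 to 0.43. There hsa-miR-4516 stayed past 2-fold, at -2.10 with TMM, -2.17 with DESeq2 and -1.94 with the authors' values, and lost its call because the interval reached 0. The ratio of hsa-miR-486-5p went under 2-fold in all 3, and that of hsa-miR-629-5p with TMM and the authors' values, while with DESeq2 it stayed at -1.02 with an interval that included 0. Summing per family, collapsing identical counts, adding 5 counts, unrounded tags and the total without the most abundant miRNA left both counts within 1.5 times. The filters at 100 CPM and no filter removed nothing and so tested nothing. With a minimum of 10 tags, 29 sequences were detected in white, 47 in purple and 29 in both. At the listing minimum of 2 tags, 67 families were detected in white, 76 in purple and 60 in both. Summed per family, the leading item took 21.6% of white and 15.3% of purple tags, and the leading 10 took 75.7% and 77.2%. No list median moved by more than the typical counting error of its members (taken from the median width of their intervals), but the let-7 cluster median fell from 0.17 to -0.32 with families of at least 100 tags and to -0.39 over single sequences. The pigment-cell median went from 0.04 to -0.36 over single sequences, and the vertebrate median from -0.06 to 0.21 with TMM and to -0.42 over single sequences. Of 87 values of named items under 3 scalings, 13 left the counting interval of the reported value and no called item changed sign. The muscle, sensory and bilaterian lists had no family with at least 100 tags, so that setting gave no value there. Correlations were called the same within 0.05, a margin set without replicates. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. Depth limits every comparison of sequences with under 10 tags.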

Other observations

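All tests in this part were chosen after the family values had been seen, as were the red-cell, white-cell, other-tissue and fragment lists, and miR-182 and miR-101 were dropped from the red-cell list at that stage, before its test was run. The red-cell families miR-451, miR-486, miR-144, miR-16, miR-92, miR-25, miR-185 and miR-363 held 583 of the white tags, or 32.0% (interval 29.9 to 34.2), and 681 of the purple tags, or 21.7% (20.3 to 23.2). The white-cell families miR-142, miR-223, miR-150, miR-146 and miR-342 held 57 white tags, or 3.13% (2.38 to 4.04), and 130 purple tags, or 4.14% (3.47 to 4.90), and miR-155 of the same list was not listed. A further 15 families were chosen for other vertebrate tissues, such as miR-122 for liver and miR-124 for brain. Of these only miR-1 and miR-128 appeared, with 17 purple tags and no white tags. Listed families outside the blood and other-tissue lists included miR-148, with 7.25% of white and 8.91% of purple tags, and miR-126, with 14 and 24 tags. The contrast with the blood families therefore depends on which families were chosen. Of the 14 blood families, miR-92 was also in the list of bilaterian families and miR-25 in the pigment-cell list, and how many the mantle itself expresses is not known here. The let-7 tags were led by hsa-let-7i-5p, with 149 of 294 in white and 185 of 406 in purple.

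The profile is thus one of sequences whose deposited entries carry vertebrate prefixes alone, in exosomes of a mussel. The lists fixed in advance include families shared across bilaterians, in the let-7 cluster, muscle, neural, epithelial, sensory and other bilaterian lists. These held 19.0% of the white and 15.5% of the purple tags. Families annotated mainly in vertebrates held more in both libraries, 55.6% and 48.6%, and none of the 16 protostome families was listed. The comparison counts each sequence once, whatever its number of entries. It was chosen once these shares were known, and the alignment settings are not given. It therefore does not decide whether conserved mussel miRNAs under vertebrate names were the source of the profile. Counted once each, the let-7 sequences shared with protostomes held 1.72% of the let-7 tags in purple and 1.36% in white. That leaves mismatched placement of mussel let-7 reads open, since such reads would leave those sequences. The share could also be higher if tags were divided among entries, since hsa-let-7a-5p had 89. Red-cell and white-cell families took 35.2% of the white and 25.8% of the purple tags, against 0% and 0.541% for the families chosen for other vertebrate tissues. These lists were drawn up once the abundant families were known, and they leave out other listed families. RNA from vertebrate blood cells was therefore not put to a test that could have failed. The source therefore stays open, since no explanation was put to a test that could have decided it.

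The miR-1246 difference is the one that stands out between the purple and the white library. Its lower interval bound was 3.45 on the log2 scale. The sequence was singled out by a rule that required this interval to exclude 0, so the bound is no separate test of counting error. The scalings tried shift every log2 ratio by -0.09 to 0.43, too little to remove this difference, and its lowest value over them was 4.28. As background, hsa-miR-1246 matches U2 small nuclear RNA and cgr-miR-1260 resembles part of a transfer RNA, while cgr-miR-1260 and hsa-miR-4532 together had 42 white and 117 purple tags, most of them from cgr-miR-1260, and a log2 ratio of 0.86 to the other listed tags, miR-1246 left out (interval 0.33 to 1.41). They were chosen after their values were seen, so more fragments of other non-coding RNA in the purple library stay open as an explanation, as do the mussel type, the animals and the preparation of the library.

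In lists chosen with the family values known, the ratio of white-cell to red-cell families, purple against white, had a log2 value of 0.96 (interval 0.47 to 1.47), and of 1.12 (0.57 to 1.68) without miR-451. Within the lists, 7 of 8 red-cell families had a log2 ratio below 0 on the share of listed tags, miR-185 being the exception, and 5 of 5 measured white-cell families were above 0, though no single white-cell interval excluded 0. The list medians were -0.59 and 0.31, at the 9.01 and 96.1 percentiles of matched random lists, and under the deposited scaling -0.16 and 0.74, where the red-cell intervals below 0 went from 3 to 0 and 1 white-cell interval lay above 0. A single change in the share of all vertebrate RNA would give every such family one ratio, but over the 22 measured families of the vertebrate list fixed in advance the chi-square was 54.0 against a 99th percentile of 38.8 in 10000 draws with one ratio (40.9 against 37.0 without miR-451). These draws hold counting error only, and the noise between single preparations was not measured, so one such change, a different mix of sources and the mussel type stay open.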
